A study of Mus musculus with 6 samples.

How the data were processed

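Gene expression was measured in hippocampi dissected from 6 mice, 3 Ahr-KO and 3 wild type, with 1 array per mouse. Ahr encodes the aryl hydrocarbon receptor, a ligand-activated transcription factor that pairs with ARNT. Total RNA was extracted with Trizol and labelled with the GeneChip WT PLUS kit for Affymetrix whole-transcript arrays, per the labels' protocols. The deposited values are log2 signals, 1 per probe set and array. RMA and Affymetrix Expression Console are named for this step per the submitters' processing notes, with no version. RMA corrects the background, quantile-normalizes the arrays together and summarises the probes of a probe set by a robust fit, so an overall shift in RNA content between arrays is removed and fold changes tend to be compressed. The annotation and genome build used for the probe sets are not given in the sources used here. No probe-level or scanner values, scan dates or detection calls were used here, so batches and the limit of detection could not be examined.

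The value table held 41345 rows. The platform annotation paired 23521 rows with 1 gene symbol, 1814 with several and 16010 with none. Symbols were updated through Entrez IDs to the RefSeq gene table of assembly GRCm38.p6, which held 23328 of the 23521 rows, and the annotation's symbol was kept for the others. Only rows with 1 symbol were tested. For the 1082 genes with several such probe sets the one with the highest mean over the 6 arrays was used, which gave 22180 genes, with no filter on dim probe sets.

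Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided moderated test, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05), on all 6 arrays and with no covariate. Residual degrees of freedom were 4 and the prior added 4.33. Differences are Ahr-KO minus wild type in log2 units, with limma's standard error (SE) and 95% interval. The labels name a different mouse for each array, so the numbers 1 to 3 do not pair mice. Between 3 and 3 arrays an exact permutation test cannot go below 0.1, so none is given. The number of arrays limits the precision.

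Before the data were examined, 31 gene lists were fixed, covering the receptor's pathway, neurogenesis, neuron types, synapses, activity-dependent and clock genes, glia, vessels, neighbouring tissues, blood, sex chromosomes and housekeeping groups. Of 794 list entries 707 were measured. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 31 lists, and again with the correlation estimated from the arrays and with fry. The score of a list on an array is the mean over its genes of the log2 value minus that gene's mean over the 6 arrays. Genes near Ahr were those within 10 Mb of it on chromosome 12 in GRCm38, compared with all other genes by a two-sided Fisher's exact test. The genes named below were also chosen by a rule fixed before the data were examined. It takes Ahr, Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1 and Arnt, the 12 genes per direction with the largest fold among those past the threshold without overlap between genotypes or, where fewer than 6 passed, 6 per direction filled by the lowest unadjusted p, and up to 3 members of each list with the lowest unadjusted p. Predicted genes, small RNAs and odorant and pheromone receptor genes were passed over for naming. Genes named outside this rule are said to be so.

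The test was tried on simulated data with the means and limma's moderated variances of the 22180 genes and 200 changed genes, over 20 simulations. It recovered 69.5% of the genes changed by 0.5 log2, 99.5% of those changed by 1 and 99.9% of those changed by 1.5, and 5.76% of its calls were false. The simulated noise was normal and independent between genes, with no shared array factor, an easier setting than the real arrays. These shares therefore do not say how many real changes would be found. In 100 simulations without any effect in which the genes of a 60-gene list shared an array factor, camera with the preset correlation gave p under 0.05 in 43%, against 6% with an estimated correlation. Without the shared factor these shares were 3% and 0%. Alternatives covered the variance model, array weights, quantile normalization and median centring, filters on dim probe sets, averaging of probe sets, a replicate block, leaving out each array, other thresholds and windows and other set tests. After the data had been seen, 3 more were added, leaving out the 2 arrays with high choroid plexus genes, using the mean of those genes as a covariate, and estimating the correlation between genes in each alternative. Figures were drawn with matplotlib 3.10.9.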

Results

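Hippocampal RNA of 3 Ahr-KO and 3 wild-type mice was profiled on 6 whole-transcript arrays, to find out which genes differ in the hippocampus when the aryl hydrocarbon receptor is missing. The labels name separate mice and give no age, and 22180 genes were tested. The arrays had closely similar distributions, with medians between 5.79 and 5.85 log2 and upper quartiles between 7.67 and 7.70. Pairs of arrays of one genotype correlated across genes at r = 0.9938 to 0.9958, and pairs of different genotypes at 0.9939 to 0.9959, with genes not being independent replicates. No 2 arrays held identical values. The first principal component took 30.1% of the variance and did not order the arrays by genotype. The second took 20.4% and placed the 3 Ahr-KO arrays between -12.3 and -6.00 and the 3 wild-type arrays between 4.09 and 11.3. Later components took 18.1%, 16.8% and 14.7%. With 6 arrays a component can separate 3 from 3 by chance, and no test of this was run. Xist, the RNA of the inactive X chromosome, lay between 4.11 and 4.37 log2 on all 6 arrays, and the Y-linked gene Uty, named outside the rule, between 7.85 and 8.19.

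Ahr, the targeted gene, was lower on every Ahr-KO array than on every wild-type array. It averaged 6.76 ± 0.15 log2 (SD, n = 3) in Ahr-KO and 7.54 ± 0.12 (SD, n = 3) in wild type, a difference of -0.78 ± 0.10 (SE), or 1.72-fold. The 3 Ahr-KO arrays read 6.62, 6.91 and 6.74 and the 3 wild-type arrays 7.68, 7.50 and 7.44. Ahr had the third lowest p of the genes tested but missed the threshold across all genes (limma, unadjusted p = 4.33e-05, adjusted p = 0.320). Which part of the gene the allele lacks and which part the single Ahr probe set reads are not given in the sources used here, and a probe outside the deleted part would not test the labels. Its signal in Ahr-KO stayed above the median of each array.

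The classical target genes of the receptor showed no difference past the threshold. Cyp1a1, Cyp1a2 and Cyp1b1, cytochromes P450 that the liganded receptor induces, differed by 0.12 (95% interval -0.13 to 0.37), 0.14 (-0.14 to 0.42) and 0.03 (-0.19 to 0.25) log2. Ahrr, the receptor's repressor, differed by -0.05 (-0.20 to 0.11) and Nqo1, a quinone reductase, by 0.04 (-0.14 to 0.23). Tiparp, an ADP-ribosyltransferase induced by the receptor, stood 0.21 higher (-0.01 to 0.44) in Ahr-KO. Of the 17 measured genes of this target list none passed over all genes or adjusted over the list alone, and at unadjusted p under 0.05 1 was higher and 0 were lower. That gene was Xdh, xanthine dehydrogenase, at 0.37 ± 0.14 (SE), and at 0.20 without Ahr-KO array 3. Gsta4, a glutathione transferase, differed by -0.11 ± 0.08 (SE). The list as a whole did not pass camera (adjusted p = 0.586). Cyp1a1, Cyp1a2, Cyp1b1, Ahrr and Xdh averaged below the array medians in both genotypes. In the list of 12 measured pathway partners, which includes Ahr, Ahr alone passed when adjusted over the list alone. Arnt, the dimerisation partner, differed by -0.16 (-0.33 to 0.02) and Ptges3, a co-chaperone of the receptor complex, by 0.29 (-0.07 to 0.65), and by 0.09 without wild-type array 1. Ptges3 averaged below the array medians in both genotypes. The list did not pass camera (adjusted p = 0.422). It passed fry's mixed test, which asks whether genes of a list change in either direction (adjusted p = 0.00939), and did not without Ahr (adjusted p = 0.538).

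**Figure D1:**
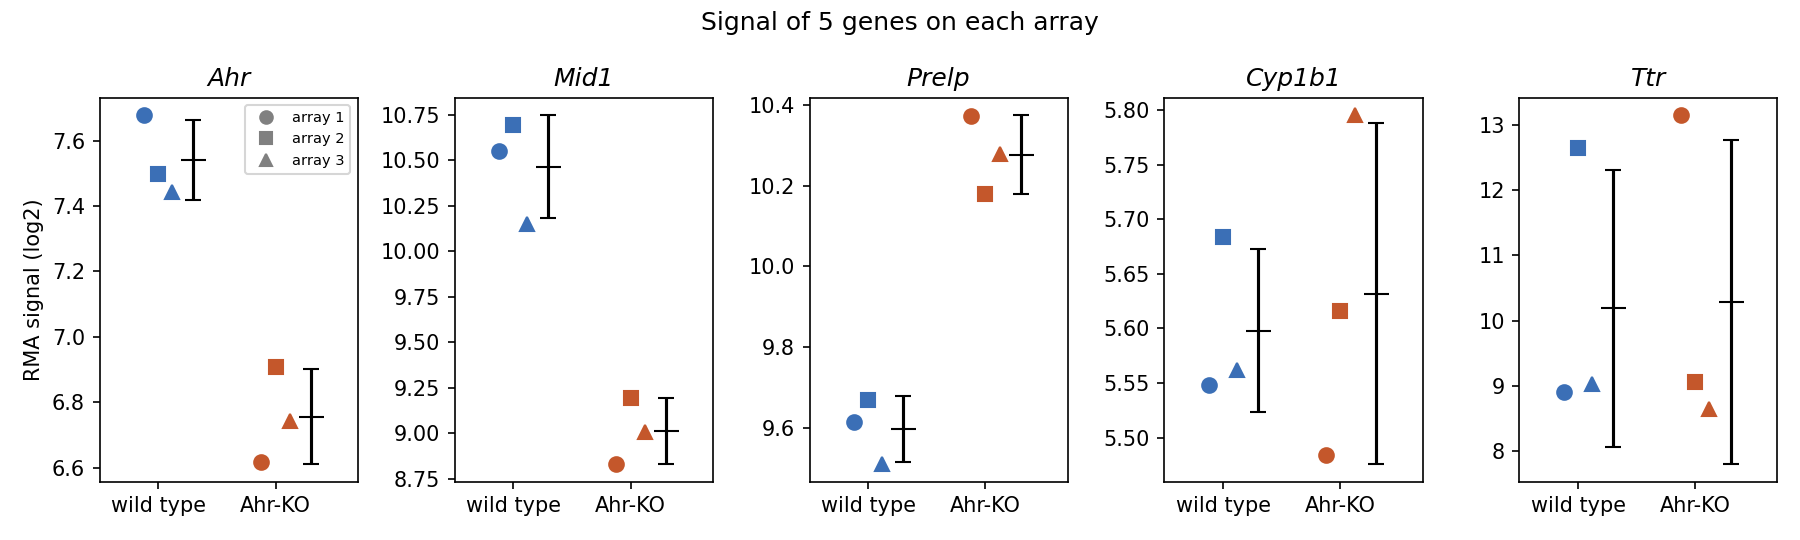
RMA signal (log2) of Ahr, Mid1, Prelp, Cyp1b1 and Ttr on each of the 6 arrays, with the symbol giving the array's number and the black bar the mean ± SD of 3 arrays. Ahr and Mid1 are lower and Prelp higher on all 3 Ahr-KO arrays, Cyp1b1 overlaps between genotypes, and Ttr is high on 1 array of each genotype (13.15 and 12.64 log2). Each panel has its own vertical scale, which does not start at 0.

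The lowest p of the genes tested belonged to Mid1, a microtubule-associated ubiquitin ligase on the X chromosome. It averaged 9.01 ± 0.18 log2 (SD, n = 3) in Ahr-KO and 10.46 ± 0.28 (SD, n = 3) in wild type, 2.74-fold lower (-1.45 ± 0.15, SE; limma adjusted p = 0.178). Prelp, a leucine-rich proteoglycan of the extracellular matrix, averaged 10.28 ± 0.10 and 9.60 ± 0.08 (SD, n = 3 each), 1.60-fold higher in Ahr-KO (0.68 ± 0.08, SE; adjusted p = 0.320). With limma, 0 genes passed adjusted p under 0.05. With an intensity trend in the variance model 2 passed, Mid1 and Prelp, at adjusted p = 0.0206 and 0.0233. Over 17 alternatives the adjusted p ran from 0.0194 to 0.780 for Mid1, the highest without wild-type array 1, and from 0.0217 to 0.973 for Prelp, the highest without Ahr-KO array 3. Both of these runs had fewer arrays, and without wild-type array 1 no gene had an adjusted p below that of Mid1. At unadjusted p under 0.05 there were 1371 genes, 784 higher and 587 lower in Ahr-KO, where 1109 are expected by chance. The share of higher genes was 57.2%, and it was 46.2% among probe sets at or above the median level and 49.6% without Ahr-KO array 2. The values of the genotypes did not overlap in 11.9% of genes, where chance gives 10%.

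The other genes with the lowest p did not pass (adjusted p = 0.428 to 0.769). Those with higher values in Ahr-KO were Psg19, a pregnancy-specific glycoprotein, at 0.60 ± 0.08 (SE), Slc22a20, an organic anion transporter, at 0.44 ± 0.08, the homeobox gene Six2 at 0.44 ± 0.09, the keratin Krt90 at 0.41 ± 0.08 and Slc5a7, the choline transporter of cholinergic terminals, at 0.40 ± 0.08. Those with lower values were Cage1 at -0.62 ± 0.12, the gasdermin Gsdma at -0.47 ± 0.08, Pcdh15, a protocadherin, at -0.41 ± 0.08 and the taste receptor Tas2r139 at -0.38 ± 0.07. Apart from Pcdh15 these averaged under the array medians in both genotypes, and Psg19 belongs to a multigene family whose probes can cross-hybridise. The second probe sets of Mid1 (mean 4.66 log2), Prelp (5.85) and Pcdh15 (6.76) differed by -0.03, 0.20 and -0.09 log2, less than the probe sets used, and the means of the probe sets of each gene by -0.74, 0.44 and -0.25.

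Lists of stem cells, immature neurons and proliferation were included because the study concerns neurogenesis, and none of the 3 passed. Doublecortin-stage and other immature-neuron genes went both ways. Draxin, an axon guidance factor, stood 0.43 ± 0.12 (SE) and Igfbpl1 0.26 ± 0.09 higher in Ahr-KO, while Stmn1, a microtubule regulator, stood 0.38 lower (-0.38 ± 0.13). Of 23 measured members 2 were higher and 2 lower at unadjusted p under 0.05 (camera adjusted p = 0.744). Among 22 stem and progenitor genes Hes5, a Notch target, and Id3, an inhibitor of basic helix-loop-helix factors, had lower values (-0.33 ± 0.10 and -0.32 ± 0.10) and Sox9 a higher one (0.24 ± 0.08), with 1 higher and 3 lower at unadjusted p (camera adjusted p = 0.925). Fry's mixed test gave adjusted p = 0.0453 for this list (unadjusted p = 0.00429). With Ahr and its neighbours left out of all lists the adjusted p was 0.0658, although this list lost no gene and its unadjusted p stayed at 0.00429, since the adjustment runs over all lists. Of 28 proliferation genes only Mcm3, a replication licensing helicase subunit, had an unadjusted p under 0.05 (0.37 ± 0.09). Tyms differed by 0.17 ± 0.09 and Ccne1 by 0.12 ± 0.09 (camera adjusted p = 0.380). No member of these lists passed over all genes or adjusted over the list alone.

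Dentate granule neuron genes had slightly higher values in Ahr-KO and passed camera with the preset correlation (adjusted p = 0.0117). With an estimated correlation the list did not pass (adjusted p = 0.899 with an estimated correlation). Of 16 measured genes 14 had a higher mean in Ahr-KO and 4 an unadjusted p under 0.05, with 0 past the threshold over all genes or adjusted over the list alone. The lowest p values belonged to Stxbp6 (0.25 ± 0.07, SE), the channel Trpc6 (0.28 ± 0.09) and Prox1, the transcription factor that specifies granule cells (0.28 ± 0.10). The list score differed by 0.10 ± 0.06 (SE) log2, and it was lowest on wild-type array 1 (-0.15). Without that array the score difference was 0.05 and the adjusted p 0.426, without wild-type array 2 the score difference was 0.15, and without Ahr-KO array 1 the adjusted p was 0.0630, within a range of 0.000310 to 0.426 over 17 alternatives. Genes of CA1 pyramidal neurons did not pass (10 genes, adjusted p = 0.744), with Wfs1 at -0.37 ± 0.19, Mpped1 at -0.17 ± 0.10 and Fibcd1 at 0.16 ± 0.09. Genes of CA2 and CA3 neurons did not pass either (16 genes, adjusted p = 0.856), with Bok at 0.22 ± 0.12, Cdh24 at -0.16 ± 0.10 and Ccdc3 at -0.14 ± 0.08. In both lists 0 genes had an unadjusted p under 0.05.

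Synaptic and dendritic genes showed no shift as groups. Of 42 glutamatergic synapse genes 1 was higher and 2 were lower at unadjusted p under 0.05, namely the postsynaptic scaffold Homer3 (0.27 ± 0.09, SE), the scaffold Dlg1 (-0.29 ± 0.11) and the AMPA receptor subunit Gria4 (-0.24 ± 0.10, and -0.15 without wild-type array 3), with camera adjusted p = 0.845. Of 27 GABAergic synapse and interneuron genes the neuropeptide Cort, made by a set of interneurons, passed when adjusted over the list alone (0.51 ± 0.11; adjusted p = 0.0419 over the list). Cort did not pass over all genes (limma adjusted p = 0.769), and the adjustment over a list takes no account of the 31 lists. Pvalb, a calcium buffer of fast-spiking interneurons, stood lower (-0.39 ± 0.12) and the interneuron transcription factor Lhx6 higher (0.24 ± 0.08), and the list did not pass camera (adjusted p = 0.856). Presynaptic vesicle genes (28 measured, adjusted p = 0.856) included Syn1 at 0.14 ± 0.08, Unc13c at -0.25 ± 0.17 and Bsn at 0.11 ± 0.08. Dendrite and spine genes (40 measured, adjusted p = 0.982) included Ephb1 at -0.18 ± 0.09, Efnb3 at 0.14 ± 0.09 and Dab1 at 0.12 ± 0.07. In the latter 2 lists 0 genes had an unadjusted p under 0.05.

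Immediate early genes, which neurons switch on with activity, had higher means in Ahr-KO for 22 of 27 genes and passed camera with the preset correlation (adjusted p = 0.0165). The list did not pass with an estimated correlation (adjusted p = 0.899 with an estimated correlation). Sik1 (0.25 ± 0.07, SE) and the nuclear receptor Nr4a3 (0.27 ± 0.10) had an unadjusted p under 0.05. Ccn1 differed by 0.51 ± 0.25, by 0.22 without Ahr-KO array 2 and by 0.34 without wild-type array 2. The list score was highest on Ahr-KO array 2 (0.24) and lowest on wild-type array 2 (-0.19), and it differed between genotypes by 0.12 ± 0.11 (SE). Without Ahr-KO array 2 the score difference was 0.04 (adjusted p = 0.472) and without wild-type array 2 it was 0.06 (0.326). Without both arrays with high choroid plexus genes (Ahr-KO array 1 and wild-type array 2) it was 0.12 (adjusted p = 0.0647, within a range of 0.00154 to 0.472 over 17 alternatives). Clock genes did not pass (17 measured, adjusted p = 0.380), with Per1 at 0.22 ± 0.10, Nr1d1 at 0.24 ± 0.12 and Ciart at 0.23 ± 0.12.

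Genes of the cytosolic ribosome and of the mitochondrial respiratory chain had slightly lower values in Ahr-KO, and both lists passed camera with the preset correlation (adjusted p = 0.00736 each). Neither passed with an estimated correlation (for each, adjusted p = 0.899 with an estimated correlation). The means were lower in Ahr-KO for 46 of 60 ribosomal genes and for 45 of 56 respiratory chain genes. The list scores differed by -0.06 ± 0.04 (SE) in both, and by -0.10 in both without Ahr-KO array 2. Rps27 (-0.46 ± 0.14), Rps16 (-0.31 ± 0.10) and Rps25 (-0.23 ± 0.10) had the lowest p among ribosomal proteins, with Cox7a2 (-0.30 ± 0.10), Cox4i1 (-0.30 ± 0.13) and the cytochrome Cyc1 (-0.23 ± 0.11) among respiratory chain subunits. Rps16 averaged below the array medians in both genotypes. Ribosomal genes did not pass without Ahr-KO array 3 (adjusted p = 0.162) or wild-type array 1 (0.216), where the score difference was -0.04 each, and respiratory chain genes did not pass without Ahr-KO array 1 (0.0650), Ahr-KO array 3 (0.0880) or wild-type array 2 (0.0620). Without the 2 arrays with high choroid plexus genes the adjusted p was 0.0647 for the ribosome and 0.310 for the respiratory chain, and over 17 alternatives it ran from 3.34e-05 to 0.216 and from 3.34e-05 to 0.310. Oxidative stress genes did not pass (20 measured, camera adjusted p = 0.586), with catalase (Cat, 0.28 ± 0.07) and the metallothioneins Mt1 (0.18 ± 0.07) and Mt2 (0.18 ± 0.08) higher at unadjusted p under 0.05.

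**Figure D2:**
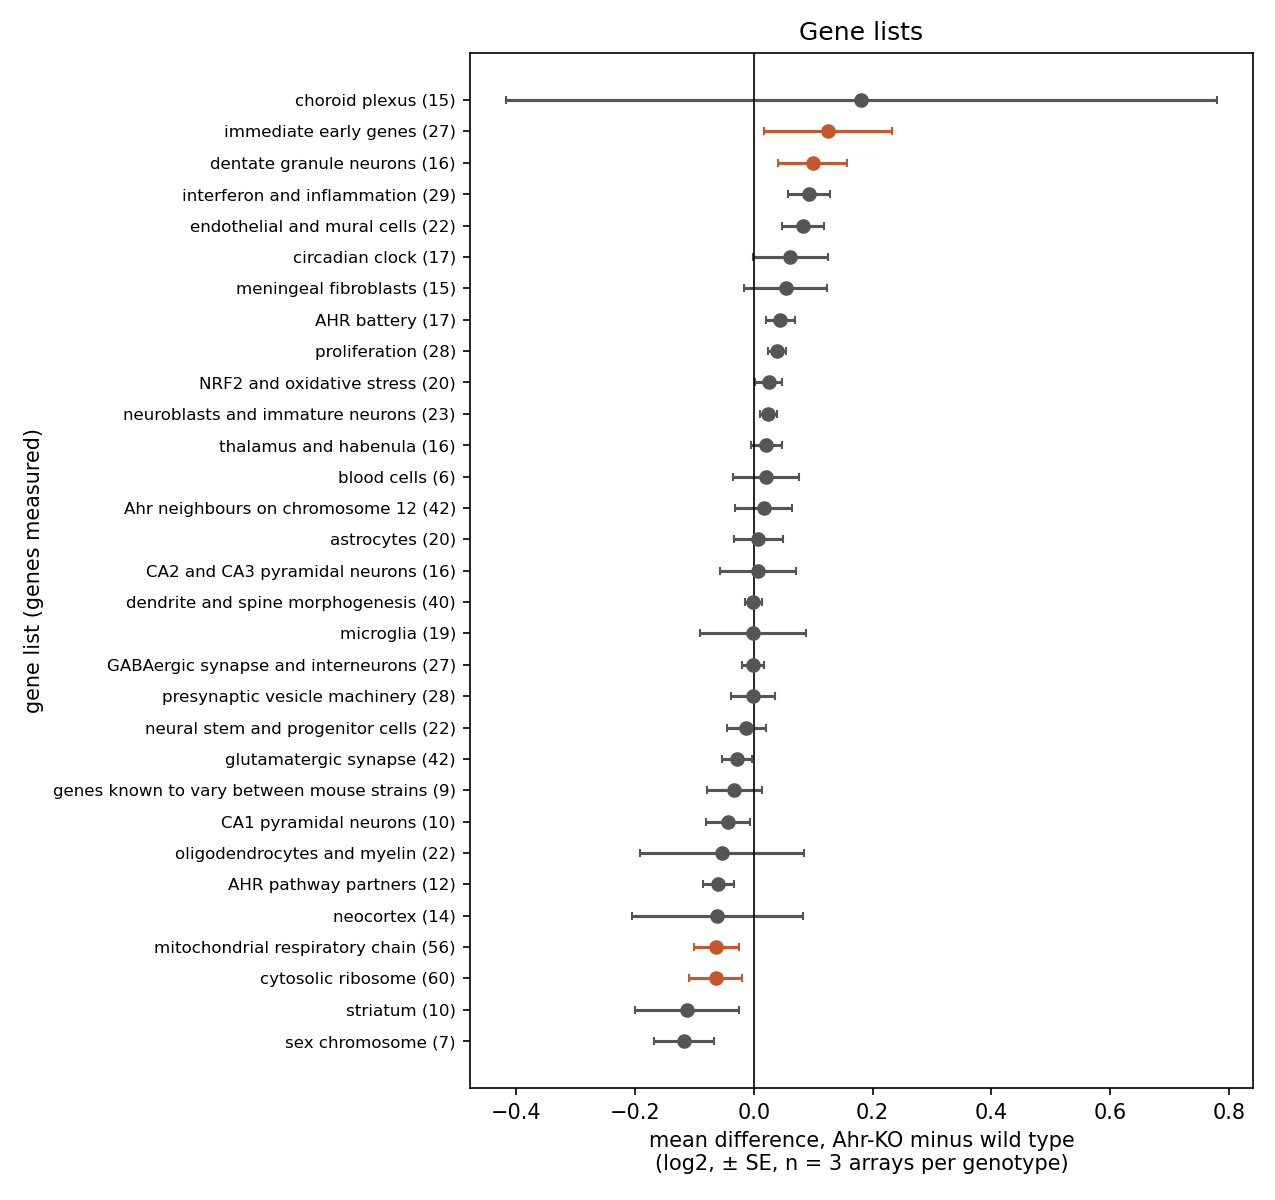
Mean difference of each of the 31 gene lists, Ahr-KO minus wild type (log2), with its SE over 3 arrays per genotype. The number of genes measured stands in brackets, and orange marks the 4 lists that passed camera with the preset correlation, none of which passed with an estimated correlation.

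Glial, vascular and immune genes showed no list past the threshold. Endothelial and mural genes came nearest (22 measured, camera adjusted p = 0.0596, and adjusted p = 0.899 with an estimated correlation), with 4 genes higher and 0 lower at unadjusted p under 0.05. These included Vwf, the von Willebrand factor (0.49 ± 0.12, SE), the smooth muscle gene Tagln (0.38 ± 0.13, and 0.23 without wild-type array 2) and the efflux transporter Abcb1a (0.19 ± 0.08). The list score differed by 0.08 ± 0.03 (SE), was highest on Ahr-KO array 3 (0.09), and without that array differed by 0.06 (adjusted p = 0.264). The list passed in 8 of 17 alternatives, among them without Ahr-KO array 1 (adjusted p = 0.0345) and without wild-type array 3 (0.0163), within a range of 0.00923 to 0.264, and in none of the 8 with an estimated correlation (adjusted p = 0.666 to 0.887 with an estimated correlation). Of 29 interferon and inflammation genes 5 were higher and 0 lower at unadjusted p. Among them were the class I antigen H2-K1 (0.31 ± 0.09), Oasl2 (0.23 ± 0.08) and Irf7 (0.25 ± 0.09), of which Irf7 averaged below the array medians in both genotypes. The list did not pass camera (adjusted p = 0.165, and adjusted p = 0.899 with an estimated correlation). Its score differed by 0.09 ± 0.04 (SE), was highest on Ahr-KO array 3 (0.11), and without that array differed by 0.06. Among probe sets at or above the median level it passed with the preset correlation (adjusted p = 0.00164, range over 17 alternatives 0.00164 to 0.408) and did not with an estimated one (adjusted p = 0.666 with an estimated correlation). Astrocyte genes went both ways, with Fgfr3 at -0.37 ± 0.09, Sox9 at 0.24 ± 0.08 and Etnppl at 0.33 ± 0.16 (20 genes, camera adjusted p = 0.856, fry's mixed test adjusted p = 0.0453). With Ahr and its neighbours left out of all lists the mixed test gave adjusted p = 0.0658, although this list too lost no gene and its unadjusted p stayed at 0.00438. Microglial genes (19 measured, adjusted p = 0.899) included Tyrobp at -0.21 ± 0.12, Siglech at -0.17 ± 0.10 and Cd68 at 0.17 ± 0.11. Among 22 oligodendrocyte genes Ermn (-0.34 ± 0.14, and -0.18 without Ahr-KO array 1) had an unadjusted p under 0.05, with Aspa at -0.25 ± 0.14 and Bcas1 at -0.17 ± 0.13 (adjusted p = 0.380). The oligodendrocyte score was lowest on Ahr-KO array 1 (-0.30). With the preset correlation the list passed as higher in Ahr-KO without that array (adjusted p = 0.0237) and as lower without Ahr-KO array 2 (0.00335) or Ahr-KO array 3 (0.0333). It passed in none of these 3 with an estimated correlation (adjusted p = 0.818 to 0.887 with an estimated correlation, and 0.940 with all arrays).

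Choroid plexus genes were far higher on 1 array of each genotype, and Ttr, Kl and F5 are named here outside the rule, after their values were seen. Ttr, the transthyretin that choroid plexus epithelium secretes, read 13.15 log2 on Ahr-KO array 1 and 12.64 on wild-type array 2, against 8.64 to 9.06 on the other 4. Kl read 9.65 and 9.27 against 7.84 to 8.12, and F5 7.77 and 6.99 against 5.14 to 5.32. Of 15 measured genes of the list 13 were higher on both arrays than on each of the other 4. Between genotypes the list did not pass (adjusted p = 0.312), with Lmx1a at 0.22 ± 0.12 (SE), Cldn2 at 0.40 ± 0.38 and Tmem72 at 0.33 ± 0.35. With the preset correlation it passed as lower in Ahr-KO without Ahr-KO array 1 (adjusted p = 0.00898) and as higher without Ahr-KO array 2 (0.0111), Ahr-KO array 3 (0.00574) or wild-type array 2 (0.00675). It passed in none of these 4 with an estimated correlation (adjusted p = 0.818 to 0.890 with an estimated correlation, and 0.940 with all arrays). Leaving out both arrays, an alternative added after seeing the data, left 0 genes past limma's threshold and 1342 at unadjusted p under 0.05.

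**Figure D3:**
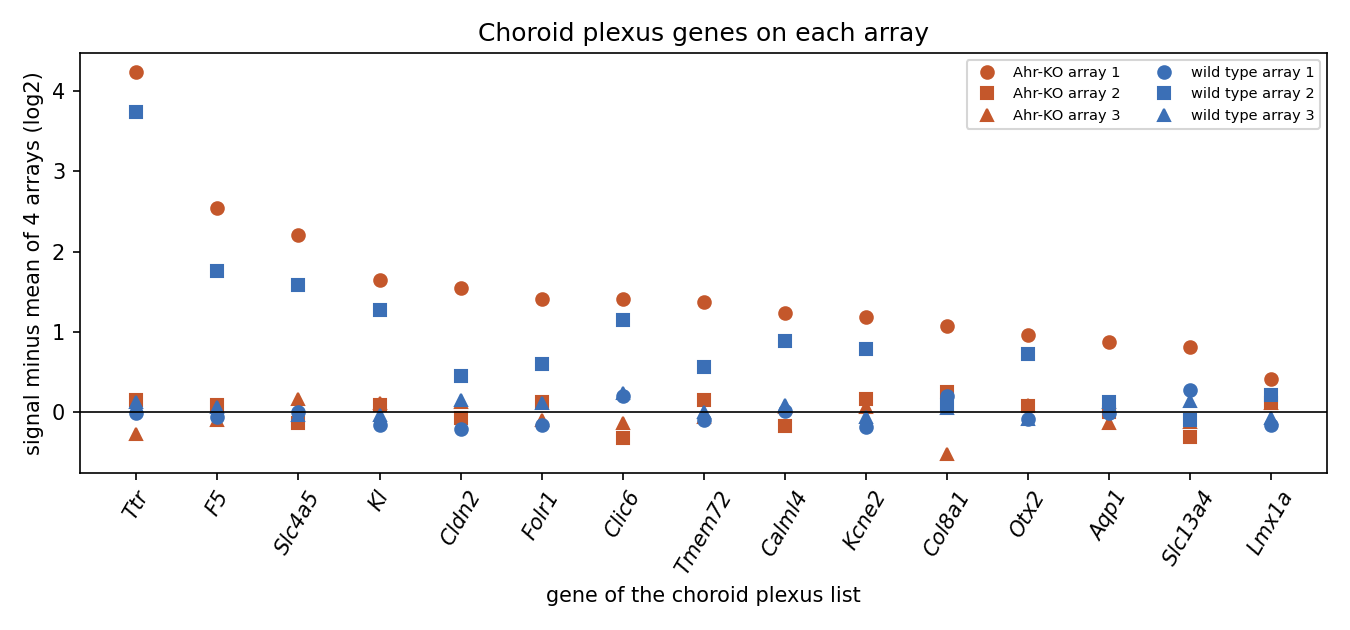
Signal of the 15 measured choroid plexus genes on each array, as log2 minus the mean of the 4 arrays with low signal. Ahr-KO array 1 and wild-type array 2 lie above the others, by a median of 1.37 and 0.73 log2.

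Lists of neighbouring tissues and blood did not pass. Meningeal fibroblast genes (15 measured, adjusted p = 0.246) included biglycan, Bgn, an extracellular matrix proteoglycan, which passed when adjusted over the list alone (0.39 ± 0.08, SE; adjusted p = 0.0170 over the list). Bgn did not pass over all genes (limma adjusted p = 0.769), and the adjustment over a list takes no account of the 31 lists. Col1a1 differed by 0.25 ± 0.09 and Ptgds by -0.32 ± 0.15. Thalamus and habenula genes (16, adjusted p = 0.744) included Tnnt1 at 0.25 ± 0.09, Calb2 at 0.31 ± 0.15 and Prkcd at -0.22 ± 0.11. Striatal genes (10, adjusted p = 0.422) included the opioid precursor Penk at -0.38 ± 0.11, Gpr6 at -0.37 ± 0.16 and the dopamine receptor Drd2 at 0.14 ± 0.08. Neocortical genes (14, adjusted p = 0.475) included Vgll3 at 0.74 ± 0.37, Cux2 at -0.27 ± 0.18 and Rorb at 0.15 ± 0.09, and the list passed as lower without Ahr-KO array 2 (adjusted p = 0.0342, and adjusted p = 0.826 with an estimated correlation) or wild-type array 2 (0.0184, and adjusted p = 0.889 with an estimated correlation). Blood genes (6 of 15 measured, adjusted p = 0.856) included Camp at 0.25 ± 0.11, Slc4a1 at 0.15 ± 0.08 and Bpgm at -0.08 ± 0.07. Sex-chromosome genes (7, adjusted p = 0.172) included the Y-linked Eif2s3y at -0.48 ± 0.15, the X-linked Kdm5c at -0.20 ± 0.08 and Xist at 0.14 ± 0.09, and the list passed among probe sets at or above the lower quartile (adjusted p = 0.0371, and adjusted p = 0.718 with an estimated correlation). Genes known to vary between mouse strains (9, adjusted p = 0.856) included Erdr1 at -0.35 ± 0.23, Gabra2 at 0.11 ± 0.12 and Cyp2d22 at 0.09 ± 0.11. In 8 of the 31 lists, those of blood, CA2 and CA3, dendrites, GABAergic synapse, glutamatergic synapse, microglia, stem cells and presynaptic vesicles, the median, the mean and the direction of the test differed in sign.

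Genes around Ahr were examined because a targeted allele brings linked DNA of the strain it was made in. Of 82 tested genes within 10 Mb of Ahr on chromosome 12 (GRCm38), not counting Ahr, 0 passed the threshold, as did 0 of 22097 others. At unadjusted p under 0.05 there were 4 of 82 (4.88%) against 1366 of 22097 (6.18%), a difference that did not pass (Fisher's exact test, two-sided, p = 0.819). The 4 were Stxbp6 (0.25 ± 0.07, SE), also in the granule neuron list, Cbll1 (0.26 ± 0.08), Twist1 (0.23 ± 0.08) and Pik3cg (-0.19 ± 0.07). The differences of the 82 genes ran from -0.25 to 0.31 log2. The fixed list of neighbours of Ahr did not pass camera (42 genes, adjusted p = 0.856).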

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

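The alternatives with the choroid plexus genes (leaving out Ahr-KO array 1 and wild-type array 2, and using the mean of these genes as a covariate) and the estimated correlation within each alternative were chosen only after the data were seen. The number of genes past adjusted p under 0.05 with limma was 0, against 1371 at unadjusted p under 0.05, and it was 2 with an intensity trend and 2 with an intensity trend and robust prior. It stayed at 0 with array weights, other scalings, filters on dim probe sets, averaged probe sets and without each array, and 13 genes had an unadjusted p under 0.05 with a fold of at least 1.5. Among probe sets at or above the median level, where fewer genes were tested, 888 genes had an unadjusted p under 0.05, of which 46.2% were higher in Ahr-KO, against 57.2% of the 1371 and 49.6% of 1602 without Ahr-KO array 2, and the cause of these shifts was not tested. The number of lists past the threshold was 4, and 0 with an estimated correlation, 0 with fry's directional test (lowest adjusted p = 0.577), 3 with its mixed test and 1 without the 2 arrays with high choroid plexus genes, where fewer arrays were tested. Leaving out single arrays gave from 2 lists (without wild-type array 1) to 6 (without Ahr-KO array 2), and each filter on dim probe sets gave 6. With the correlation estimated in each of 17 alternatives the number was 0 (lowest adjusted p = 0.666 with an estimated correlation). The 2 settings with an intensity trend do not enter camera. Counts and ranges of lists over 17 alternatives therefore hold 2 repeats of the main result. The odds ratio of genes at unadjusted p near Ahr was 0.778 and ran from 0.567 without wild-type array 1 to 1.22 without wild-type array 3, and was also above 1 without Ahr-KO array 1 (1.03) and Ahr-KO array 2 (1.01). The cause was not tested. Ahr kept its direction, at -0.86 to -0.71 without single arrays, and did not pass in any alternative. Of 1791 alternative values of the other 107 named genes 5 changed sign. Many of these values could not change sign. The intensity trend, the replicate block and the filters on dim probe sets leave a gene's difference as it was, and median centring hardly moves it. The count therefore overstates how far the directions were tested. Of the 108 named genes 46 moved by over 1.5 times or changed sign without 1 array, 4 of them with an unadjusted p under 0.05. Without single arrays Nqo1 ran from -0.0050 to 0.084, Cldn2 from -0.11 to 0.70 and Tmem72 from -0.11 to 0.61, each negative without Ahr-KO array 1, and Cyp1b1 ran from -0.048 to 0.11, negative without Ahr-KO array 3. Nqo1 was also negative without the 2 arrays with high choroid plexus genes (-0.015). The cause was not tested. Signal over background could not be judged, since no detection calls were used.

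The replicate numbers did not pair the mice. Deviations from the group means correlated across genes at -0.15, -0.22 and 0.05 between arrays of the same number, and Ahr-KO array 1 correlated best with wild-type array 2 (0.18) and Ahr-KO array 2 with wild-type array 1 (0.23). With the replicate block 0 genes passed (limma, lowest adjusted p = 0.354) and 1122 had an unadjusted p under 0.05. In this fit 4 lists passed camera at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.921). The odds ratio near Ahr was 1.22. The cause was not tested.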

Other observations

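The tests of choroid plexus tissue and of the genes around Mid1 were chosen only after the results they bear on were seen, as were the genes and probe sets named in the next 2 paragraphs, while the estimated correlation was planned and only its use for members of a list varying together came after its result.

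Small leucine-rich proteoglycans of the extracellular matrix went both ways. Of 15 measured, Prelp (0.68 ± 0.08, SE) and Bgn (0.39 ± 0.08) were higher in Ahr-KO at unadjusted p under 0.05, Ogn (-0.60 ± 0.17) and Aspn (-0.37 ± 0.11) were lower, and 11 were neither, among them Dcn (-0.05 ± 0.33) and Lum (0.10 ± 0.13). None passed limma's adjusted threshold. The 4 directions held after quantile normalization and after median centring, which does not test scaling, since the deposited values were already normalized. A less bright probe set of Bgn differed by 0.24 and one of Prelp by 0.20.

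Lcn2, an iron-carrier-binding protein induced in inflammation, read 8.63 log2 on Ahr-KO array 3, against 6.30 and 6.42 on the other Ahr-KO arrays and 5.70 to 5.96 in wild type (1.25 ± 0.53, SE; limma adjusted p = 0.806). Among the 17824 rows without a single gene symbol, fitted apart, 0 passed with limma and 969 had an unadjusted p under 0.05. The lowest adjusted p, 0.116, belonged to the unnamed probe set 17206597, which was 1.80 ± 0.14 (SE) log2 higher in Ahr-KO.

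Choroid plexus genes were high on Ahr-KO array 1 and wild-type array 2. On both arrays 13 of 15 genes were higher than on each of the others, and wild-type array 2 lay above both Ahr-KO arrays 2 and 3 in 14 of 15. These counts restate the pattern and do not test choroid plexus tissue as its source. With 1 high array in each genotype, the pattern does not follow the genotypes. Choroid plexus tissue taken along in 2 dissections stays open as a candidate explanation. A genotype difference in these genes beside this pattern was not tested apart from it (list score 0.18 ± 0.60, SE). Ttr, abundant in choroid plexus epithelium, exceeded the mean of the other 4 arrays by 4.24 and 3.73 log2, no gene of this list is in another list, and 3 of 15 lay above the array median on all of the other 4 arrays.

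4 lists passed with the preset correlation. With the choroid plexus mean as a covariate all 4 passed at the preset correlation. In every alternative 0 lists passed with an estimated correlation (lowest camera adjusted p = 0.666). Since 1 array of each genotype was high, the covariate was nearly balanced between genotypes and could hardly alter their difference. It cannot decide whether choroid plexus tissue on 2 arrays is a source of the 4 calls. Without those 2 arrays, where fewer arrays were tested, 1 passed, and the score differences were -0.05 ± 0.07 (SE) for the ribosome (-0.06 ± 0.04 with all arrays), 0.12 ± 0.12 for immediate early genes (0.12 ± 0.11), -0.04 ± 0.06 for the respiratory chain (-0.06 ± 0.04) and 0.14 ± 0.05 for granule neurons (0.10 ± 0.06). Members of a list varying together between arrays within a genotype may give such calls. In simulations without an effect, a 60-gene list with a shared array factor had camera p under 0.05 in 43% with the preset correlation. Smaller lists were not simulated. With an estimated correlation 0 of the 4 passed, but 0 of the 31 lists had even an unadjusted p under 0.05. A shift together with a shared factor was not simulated, so how often this test would find one is not known. Its misses therefore decide nothing. A genotype effect stays open and was not tested apart from such shared variation.

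Mid1 was lower on all 3 Ahr-KO arrays, with a difference of -1.45 log2. Scaling between arrays could not be tested, since the deposited values were already normalized. Quantile normalization and median centring moved the median difference of the genes by -0.0025 and -0.00079 log2, and the smaller Mid1 difference after them was -1.45. A segment of another strain around Mid1 stays open as a hypothesis. Such a segment would not be linked to Ahr, since Mid1 lies on the X chromosome and Ahr on chromosome 12. Within 10 Mb of Mid1 (GRCm38) 1 of 55 genes had an unadjusted p under 0.05 (1.82% against 6.19% of other genes, Fisher's exact test, two-sided, p = 0.261). This decides nothing, as a segment could alter Mid1 alone. The largest difference among these neighbours was that of Erdr1, of the list of genes known to vary between strains (-0.35 ± 0.23, SE; limma unadjusted p = 0.165). Within each genotype the arrays had the same order in Erdr1 as in Mid1. In wild-type arrays 1 to 3 Mid1 read 10.55, 10.69 and 10.15 and Erdr1 11.19, 11.37 and 10.41. Erdr1 overlapped between genotypes, and what it shares with Mid1 was not tested. An effect of the Ahr genotype stays open too, and the second, dim probe set of Mid1 differed by -0.03.

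The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past adjusted p with limma, so the count of splits with at least as many says nothing, and the highest of the others gave 7. For genes at unadjusted p under 0.05 the real split gave 1371 and the highest other 1811, with 3 splits at least as high, the real one included. For lists these were 4 and 12, with 7 splits, again including the real one. The highest in each case was Ahr-KO arrays 1 and 3 with wild-type array 2 against the rest, with both arrays with high choroid plexus genes on one side. The first principal component separated the same arrays, and Ttr, of the choroid plexus list, had the largest weight in it. Other splits also had both arrays with high choroid plexus genes on one side. With wild-type array 3, wild-type array 1 or Ahr-KO array 2 beside them there were 1399, 905 and 761 genes at unadjusted p under 0.05. The lists past the threshold were 7, 5 and 4. Having both arrays on one side thus did not by itself go with a high count. No explanation of the highest split was tested.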
